A study of Mus musculus with 6 samples.

How the data were processed

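Total RNA of 6 C2C12 samples, 3 with a control siRNA and 3 with an siRNA against lncMGPF, was labelled with Cy3 and hybridised to 1-colour Agilent mouse arrays, per the labels. Samples were grouped by the siRNA in their labels. The deposited scanner tables hold intensity values on a linear scale, which Feature Extraction 11.0.1.1 had background-subtracted and detrended, per the file headers. The authors' series table holds the same intensity values without scaling between arrays: it equalled the processed signal at 44397 of 44397 spots on each array, compared as numbers with no tolerance. Its median was 70.25, 54.17 and 59.89 on si-NC replicates 1, 2 and 3, and 74.34, 42.8 and 38.31 on si-lncMGPF replicates 1, 2 and 3. The authors' tests are not given in the sources used here.

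The 43020 non-control spots held 39429 probes. Spots marked as outliers were left out (117 to 134 per array), and no spot was saturated. Values were log2 of the processed signal minus the array's 75th percentile of it, with spots of a probe averaged. This scaling sets the 75th percentile equal between arrays, so a shift of most transcripts in 1 direction cannot be seen. A probe was tested if it was well above background on every array of at least 1 group. That left 24661 probes, of which 21560 were above background on all 6 arrays. The mean net signal of negative control spots was 20.1 to 21.82 on slide 1 and 37.29 and 42.49 on slide 2, so dim probes are measured less well on slide 2.

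The scanner tables hold accessions without gene names. An accession, with its version removed, was matched to a RefSeq gene table of another genome build than that of the array, used for names only. It named 27234 probes (20659 genes), and 12195 stayed without a name. Of the tested probes 18528 were named, for 14265 genes. The probe with the highest mean signal stood for a gene. Positions are not given because the builds differ, and probe sequences were not used here.

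Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05 for the adjusted p. Folds are linear ratios computed from log2 differences. Gene lists, 29 in number, were tested against the other genes with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the lists, and again with an estimated correlation. Limma's fry, run beside it, tests whether a list's genes change at all and does not compare them with the other genes. The comparison, the lists, the rule for named genes and most alternatives were set before the data were examined. Genes were named if they were myogenic transcription factors, Elavl1, Actb or Gapdh, or if they were among the 12 with the largest rise or fall past the threshold without overlap of the groups and above background on all arrays. Clones and predicted genes were left out. For each list up to 4 members past the threshold and its brightest other member qualified, as did up to 5 genes per direction measured in 1 group alone. Further list members are given where they passed when adjusted over the list alone or had small p, and were chosen after their values were seen; the value of 1 list member is not reported here.

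On simulated data with the spread of these arrays, 200 of 24617 probes were changed in each of 10 runs. The test recovered 17.2% of probes changed 1.5-fold, 78.7% of those changed 2-fold and 97.1% of those changed 4-fold, with 6.62% of calls false. Noise was drawn independently for each array without a slide effect. These shares therefore need not hold for the real arrays, where slide and group are partly confounded. For gene lists simulated over 14244 genes, a list of 40 genes shifted by 0.3 on the log2 scale was called in 10 of 10 runs and 0 of 190 unshifted lists were called. That error rate does not carry over to these arrays, where each of the 9 other splits of the arrays called 1 to 8 lists.

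Alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, other filters on dim probes, an intensity trend with a robust prior, array weights, slide and replicate number as blocks, the series table's values, a test for a fold over 1.2, the mean of a gene's probes, and leaving out each array in turn. Normexp was planned on mean spot signals, a column the tables used here lack, and ran on median spot signals. Chosen after seeing the data were that normexp run, the slide 1 arrays alone, slide as a random block, removal of a signal trend within each array, and array weights by the gene-by-gene method. Figures were drawn with matplotlib 3.10.9.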

Results

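The samples were 6 RNA preparations of C2C12, a mouse myoblast line that leaves the cell cycle and fuses into myotubes when it is induced to differentiate. In 3 samples the cells carried a control siRNA (si-NC), and in 3 they carried an siRNA against the long noncoding RNA lncMGPF (si-lncMGPF). All were taken after 2 days of differentiation, and total RNA was read on 1-colour expression arrays. The 75th percentile of the signal was 930.7, 688.2 and 755.1 intensity units on si-NC replicates 1, 2 and 3. On si-lncMGPF replicates 1, 2 and 3 it was 923, 580.2 and 492.1. The scan identifiers put the 3 si-NC arrays and si-lncMGPF replicate 1 on slide 1, and si-lncMGPF replicates 2 and 3 on slide 2. Between 64.13% and 65.28% of probes were well above background on the slide 1 arrays, against 57.3% and 56.93% on slide 2. Correlations of log2 signal ranged from 0.994 to 0.999 between arrays of 1 group on 1 slide, from 0.993 to 0.995 between groups on slide 1, from 0.987 to 0.991 between slides across groups, and from 0.987 to 0.988 between slides within si-lncMGPF, so si-lncMGPF replicate 1 correlated better with the si-NC arrays on its slide than with its own group. The first principal component held 57.67% of the variance, with the slide 2 arrays at 40.87 and 45.91 and the slide 1 arrays between -23.14 and -19.59. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

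The comparison asks which genes change when lncMGPF, an RNA tied to myogenic differentiation, is knocked down. No probe carried that name, so the level of the target was not checked here.

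Clu, which encodes the extracellular chaperone clusterin, fell 2.69-fold (log2 change -1.43, SE 0.09, adjusted p = 0.0147). Atp13a4, a cation-transporting ATPase, fell 3.19-fold (log2 change -1.67, SE 0.09, adjusted p = 0.00941). Myl2, the regulatory light chain of slow-twitch and cardiac myosin, fell 2.85-fold (log2 change -1.51, SE 0.12, adjusted p = 0.0216). Enpp2, which encodes autotaxin, the enzyme that makes lysophosphatidic acid, rose 2.08-fold (log2 change 1.05, SE 0.08, adjusted p = 0.025).

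In all, limma called 26 of 24661 probes at an adjusted p below 0.05, 7 higher and 19 lower in si-lncMGPF, and 18 of them had a fitted difference of at least 2-fold (4 higher, 14 lower), 7 of these not well above background on every si-lncMGPF array. With 1 probe per gene, 21 of 14265 genes passed, 6 higher and 15 lower. Gzme, a granzyme, had a log2 change of -1.32 on 1 probe and -1.08 on another, both past the threshold. The trypsin gene Try4 fell by 1.34 and the mast cell protease gene Mcpt4 by 0.75 on the log2 scale. Fxyd6, a regulator of the sodium pump, fell by 1.28, and Plch1, a phospholipase C, by 0.85. The lectin gene Colec10 fell by 0.87, the membrane glycoprotein gene Gpnmb by 0.88 and the osteocalcin gene Bglap2 by 0.84. Higher in si-lncMGPF, beside Enpp2, were Prl2c1 of the prolactin family (log2 change 0.98), the glutathione S-transferase gene Gsta2 (0.97) and Nqo1, a quinone reductase (0.96). The called genes Gm3776 (1.41), Gm10639 (1.18, and 0.59 on a second probe that did not pass) and the proton pump subunit gene Atp6v1c2 lie outside the rule for named genes and were chosen after their values were seen. Gsta2, Gm3776, Gm10639, Gzme, Prl2c1 and Bglap2 belong to families of near-identical transcripts, so their signals are uncertain.

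Il7r, Mmel1 and Ms4a18 were not well above background on any si-lncMGPF array, and Atp6v1c2 on 1 alone, so their fold is a bound. It sets the mean of the si-NC arrays against the higher of the probe's own signal and the lowest signal well above background on each si-lncMGPF array. Il7r, a receptor of interleukin 7, was at least 1.57-fold lower (adjusted p = 0.0363). The peptidase gene Mmel1 was at least 1.2-fold lower (adjusted p = 0.00941) and Ms4a18 at least 1.02-fold lower (adjusted p = 0.0363). Atp6v1c2 was at least 1.92-fold lower (adjusted p = 0.0363). These bounds hold for the main processing alone. After normexp the log2 changes were -0.13 for Il7r, -0.03 for Mmel1, 0.09 for Ms4a18 and -0.09 for Atp6v1c2. Each fell short of its bound, and Ms4a18 changed direction.

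**Figure D1:**
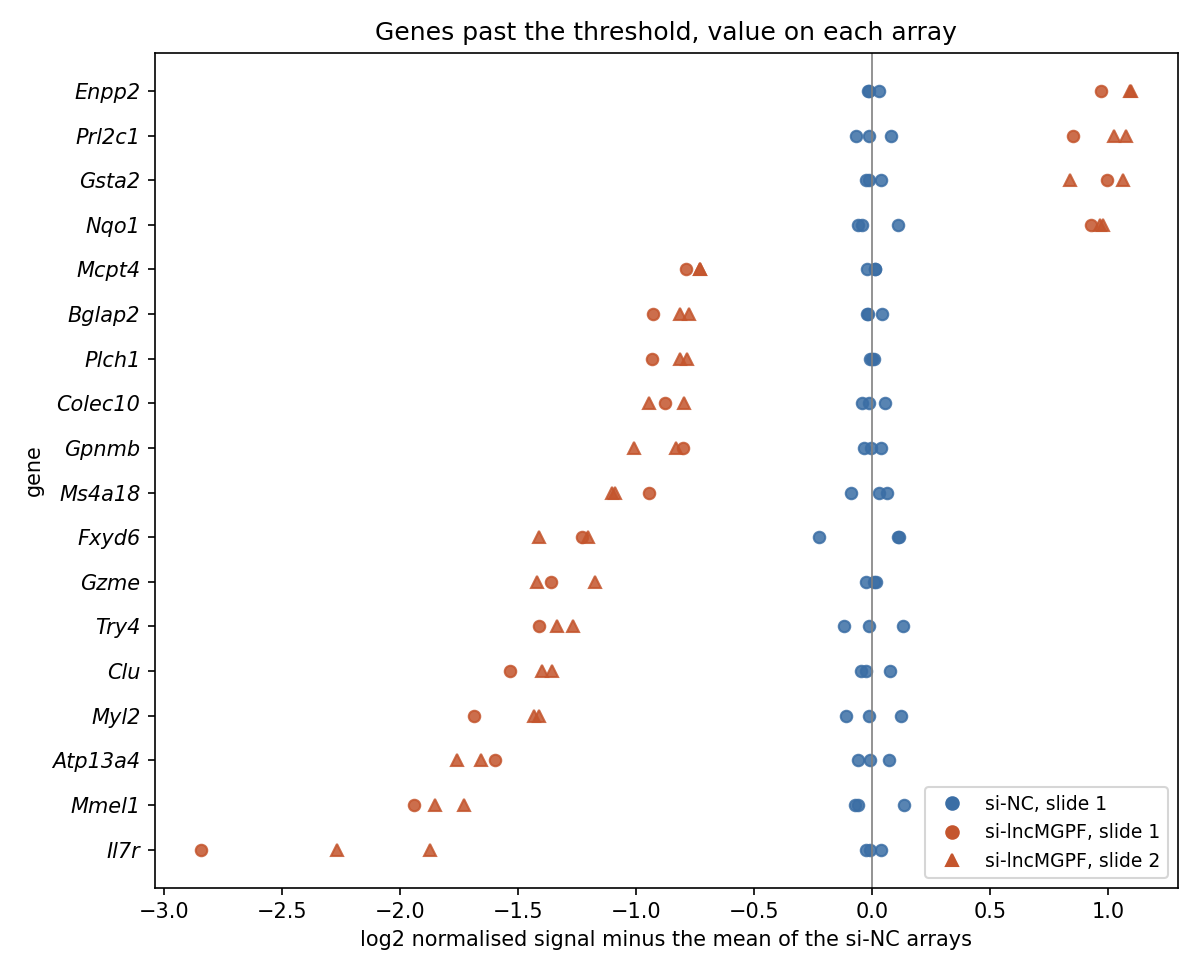
Log2 normalised signal of each named gene past the threshold, minus the mean of the 3 si-NC arrays (x axis, log2 units; genes on the y axis); each point is 1 array, coloured by group, with circles for slide 1 and triangles for slide 2. On each line the 3 si-lncMGPF arrays lie apart from the 3 si-NC arrays, as the selection of these genes favours. Genes above background on all arrays run from Atp13a4 (log2 change -1.67) to Enpp2 (1.05). Values of Il7r, Mmel1 and Ms4a18 in si-lncMGPF are not well above background.

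The 2 groups of arrays did not overlap for any of the 26 probes, which selection by adjusted p favours. Of all tested probes 22.9% showed no overlap, where chance gives 10% if arrays are interchangeable. With 2 of the 3 si-lncMGPF arrays alone on slide 2, slide can raise that share, so it does not single out the knockdown. Within slide 1, where 1 si-lncMGPF array stood against 3 si-NC arrays, the change was -1.53 for Clu, -1.60 for Atp13a4, -1.69 for Myl2 and 0.97 for Enpp2. A fit with slide as a block estimates this same change, because slide 2 holds no si-NC array. Its group effect, and so its calls, rest on 1 si-lncMGPF array and are no separate check. The si-lncMGPF array lay beyond the si-NC range in the same direction for 26 of the 26 probes, which selection by the fit over all arrays favours. After normexp background correction the log2 change was -0.85 for Clu, -0.88 for Atp13a4, -0.74 for Myl2 and 0.92 for Enpp2. Of the 21 called genes 13 shrank by over 1.5 times or changed sign. The offset of 50 lies among the median signals of the arrays (38.31 to 74.34), so log2 changes of dim probes shrink by construction. How much of the shrinkage comes from the offset was not tested. With slide as a block, limma called 10 probes (3 higher, 7 lower), and 5 were shared with the 26: those of Il7r, Mmel1, Atp13a4, Clu and Myl2, with adjusted p from 0.0378 to 0.0421. After normexp none of these 5 genes passed (adjusted p from 0.171 to 0.933; over all settings from 0.00025 to 0.933). For Enpp2 the blocked adjusted p was 0.0719, for Gzme 0.0769 and for Nqo1 0.112. The count was 0 without si-NC replicate 1, 2 or 3 or without si-lncMGPF replicate 3, with 2696, 1925, 1877 and 2232 probes at an unadjusted p below 0.05, against 3904 with all arrays. It was 4 without si-lncMGPF replicate 2 and 4105 without si-lncMGPF replicate 1, when group and slide coincide.

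None of the 18 tested myogenic transcription factors passed the threshold, and 0 passed when adjusted over the list alone (limma, 2 higher and 1 lower at an unadjusted p below 0.05). Myod1, which commits cells to the muscle lineage, had a log2 change of 0.06 (SE 0.11, 95% interval -0.20 to 0.31). Myog, which drives terminal differentiation, had 0.09 (SE 0.10, 95% interval -0.14 to 0.32). Mef2c, a partner of these factors, had 0.78 (SE 0.21, adjusted p = 0.223), with 0.27 within slide 1 and 1.03 on slide 2 against the same si-NC arrays. Its probe was dim (mean log2 normalised signal -5.18 in si-NC). Negative control spots read higher on slide 2 (37.29 and 42.49) than on slide 1 (20.1 to 21.82), so the slide 2 value of Mef2c is less certain. Myf5, a factor of undifferentiated myoblasts, had -1.20 (SE 0.40, adjusted p = 0.258), with -0.21 within slide 1 and -1.69 on slide 2. Myf6 had 0.41 (SE 0.11, adjusted p = 0.221) and Pax3 0.56 (SE 0.26, adjusted p = 0.347), with 0.55 and -0.08 within slide 1. Without si-lncMGPF replicate 1, group and slide coincide, and 4105 of 24661 probes passed the threshold. Mef2c, Myf5 and Pax3 were among them, with log2 changes of 1.03, -1.69 and 0.87, and slide and knockdown cannot be told apart there. Elavl1, which encodes the RNA-binding protein HuR, had 0.07 (SE 0.18), Actb 0.20 (SE 0.21) and Gapdh 0.13 (SE 0.23). Other probes of Gapdh had 0.09 to 0.36, none past the threshold. A second probe differed in sign from the first for Mef2a (-0.27 against 0.003) and Tcf12 (-0.34 against 0.13).

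**Figure D2:**
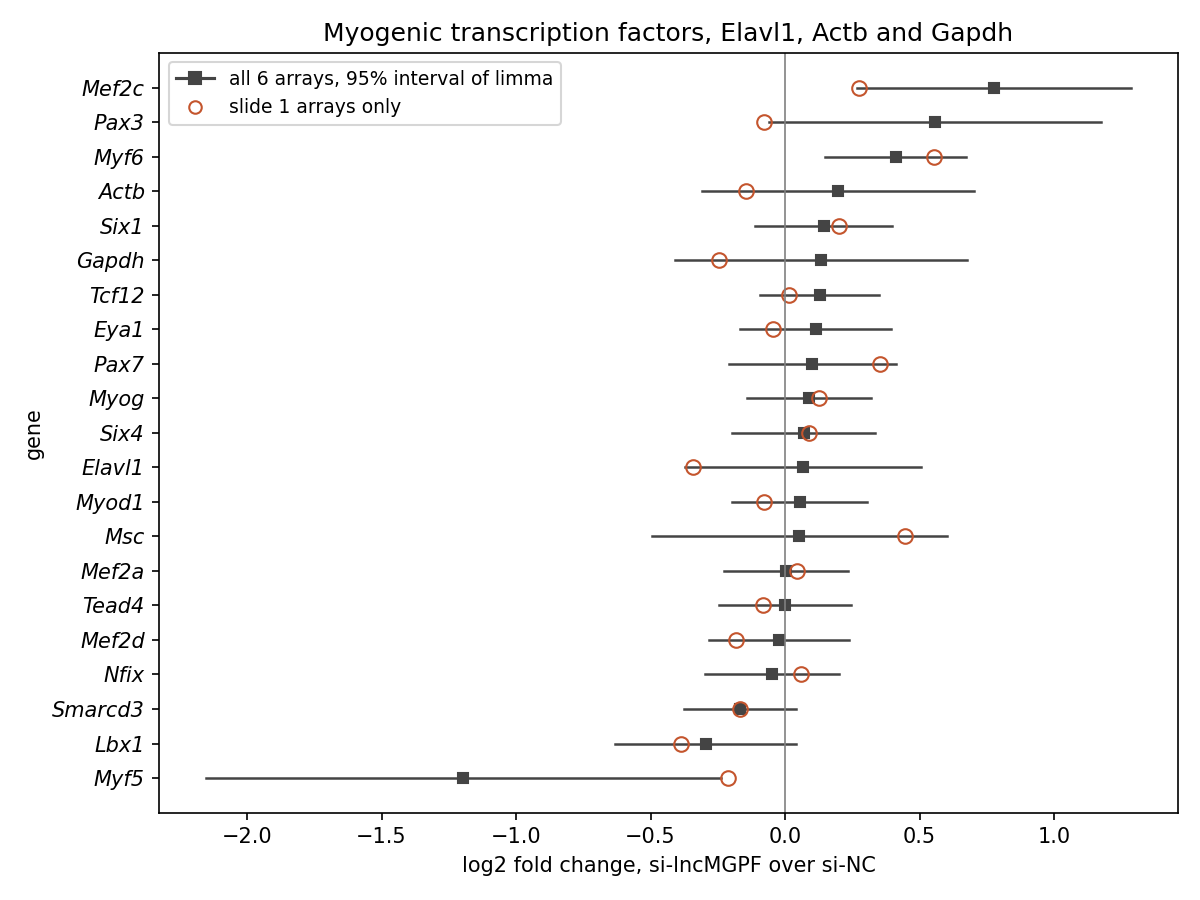
Log2 fold change of si-lncMGPF over si-NC (x axis, log2 units) for the tested myogenic transcription factors, Elavl1, Actb and Gapdh (y axis); squares are all 6 arrays with limma's 95% interval and open circles the slide 1 arrays alone. Mef2c lies at 0.78 over all arrays and at 0.27 on slide 1, Myf5 at -1.20 and -0.21.

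Of 57 sarcomere genes 43 had a negative log2 change, and the list stood below the other genes by camera, with a median of -0.12 (adjusted p = 0.000225; adjusted p = 0.78 with an estimated correlation). Myl2 was the member past the threshold over all probes, and 5 members fell when adjusted over the list alone. Beside Myl2 these were Myh7 (log2 change -0.64) and Myh4 (-0.60), heavy chains of slow and fast myosin, Neb (-0.72), the nebulin of thin filaments, and Tcap (-0.43), a Z-disc protein. The excitation-contraction coupling list was also lower (22 genes, median -0.14, adjusted p = 0.03; adjusted p = 0.78 with an estimated correlation), with 0 members past the threshold over all probes and 4 lower when adjusted over the list alone. These were Pvalb (-0.60), a calcium buffer, Atp2a2 (-0.48), a calcium pump, Cacna1s (-0.46), a calcium channel, and Hrc (-0.40). Another probe of Atp2a2 had a positive change and another of Neb a smaller fall, with values given below. Muscle energy metabolism did not pass as a list (23 genes, median -0.03, adjusted p = 0.104). Adjusted over the list alone, 4 of its members were lower, namely Fabp3 (-0.61), a fatty acid carrier, Trim72 (-0.53), Pygm (-0.38) and Cox6a2 (-0.36). Nor did myoblast fusion and adhesion (27 genes, adjusted p = 0.952), where Cav3 (-0.60) and Dysf (-0.39), proteins of the muscle membrane, were lower when adjusted over the list alone. The acetylcholine receptor list (12 genes, median -0.12, adjusted p = 0.187) had 0 members past either threshold.

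In the sarcomere, coupling, energy metabolism and fusion lists, 15 genes were lower when adjusted over their list alone. Within slide 1 all 15 were also lower and beyond the si-NC range. Selection by the fit over all arrays favours that, and it rests on 1 si-lncMGPF array. The slide 1 medians of whole lists were -0.03 for sarcomere and 0.02 for excitation-contraction coupling. With slide as a block neither list was called, at adjusted p of 0.927 and 0.812. Over all 29 lists, camera with a preset correlation called 9, 5 higher and 4 lower, and 0 held with an estimated correlation (lowest adjusted p = 0.78 with an estimated correlation). Adjustment gives many lists that same 0.78, and the lowest unadjusted p of camera with an estimated correlation was 0.117, for cholesterol synthesis. That correlation is estimated from residuals that hold the slide difference within si-lncMGPF. Failing this test therefore does not show that a list is unchanged. Tested against no change and not against the other genes, fry called 0 for a one-directional shift and 17 for change in either direction.

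Lists of metabolic and broadly expressed genes, 5 in number, stood higher in si-lncMGPF over all arrays by camera, each with an adjusted p = 0.78 with an estimated correlation. The housekeeping list shares members with others, such as Pgk1 with glycolysis, Sdha with oxidative phosphorylation, and Rps18 and Rplp0 with ribosomal proteins. These lists are therefore not separate support. Hypoxia and glycolysis had a median log2 change of 0.28 over 28 genes, 28 of them positive (adjusted p = 3.08e-06). Members with the smallest p were Ankrd37 (0.47), Pgk1 (0.45) and Egln3 (0.41). Cytosolic ribosomal proteins had 0.22 over 45 genes (adjusted p = 1.19e-06), with Rps2 at 0.45 and Rpl3 at 0.28. Cholesterol synthesis had 0.18 over 30 genes (adjusted p = 0.000772), with Cyp51 (0.35) and Insig1 (0.32). Oxidative phosphorylation had 0.12 over 38 genes (adjusted p = 0.00377), and the housekeeping list had 0.25 over 19 genes (adjusted p = 0.000772). In these 5 lists 0 members passed the threshold, over all probes or when adjusted over the list alone, and each median stayed above 0 under the other scalings. With quantile normalization the ribosomal median was 0.111 and that of housekeeping genes 0.149, and with normexp oxidative phosphorylation had 0.0821, where all genes had 0.064. For scale, the brightest of 5 bins of tested probes by mean signal had a median change of -0.112 within slide 1 and 0.129 on slide 2. Within slide 1 the medians were 0.02, -0.03, 0.03, -0.03 and 0.02 in the same order, and with slide as a block none of the 5 was called (adjusted p from 0.0972 to 0.625).

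Interferon and double-stranded RNA response genes, which cells switch on when they sense foreign RNA, were lower (44 genes, 30 negative, median -0.11, adjusted p = 0.0139; adjusted p = 0.78 with an estimated correlation). The median within slide 1, from 1 si-lncMGPF array, was -0.23, and that of the slide 2 arrays against the same si-NC arrays -0.000644. The list was called with slide as a block (adjusted p = 0.000791; 0.816 with an estimated correlation). Xaf1 (log2 change -0.51) was lower when adjusted over the list alone, and 0 members passed over all probes. Cxcl10 had 0.50. The S and G2/M phase list had a median of 0.02 over 62 genes (adjusted p = 0.952), with -0.25 within slide 1, from 1 si-lncMGPF array, and 0.14 on slide 2, and it was called lower with slide as a block (adjusted p = 0.00919; slide-blocked estimated-correlation adjusted p of at least 0.816 for every list). Rrm2 had 0.08. The smooth muscle list was lower (12 genes, median -0.11, adjusted p = 0.0242; adjusted p = 0.78 with an estimated correlation), at -0.19 within slide 1 and -0.11 on slide 2 (adjusted p = 0.0972 with slide as a block), with Myl9 (-0.57) and Actg2 (-0.48) lower when adjusted over the list alone.

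**Figure D3:**
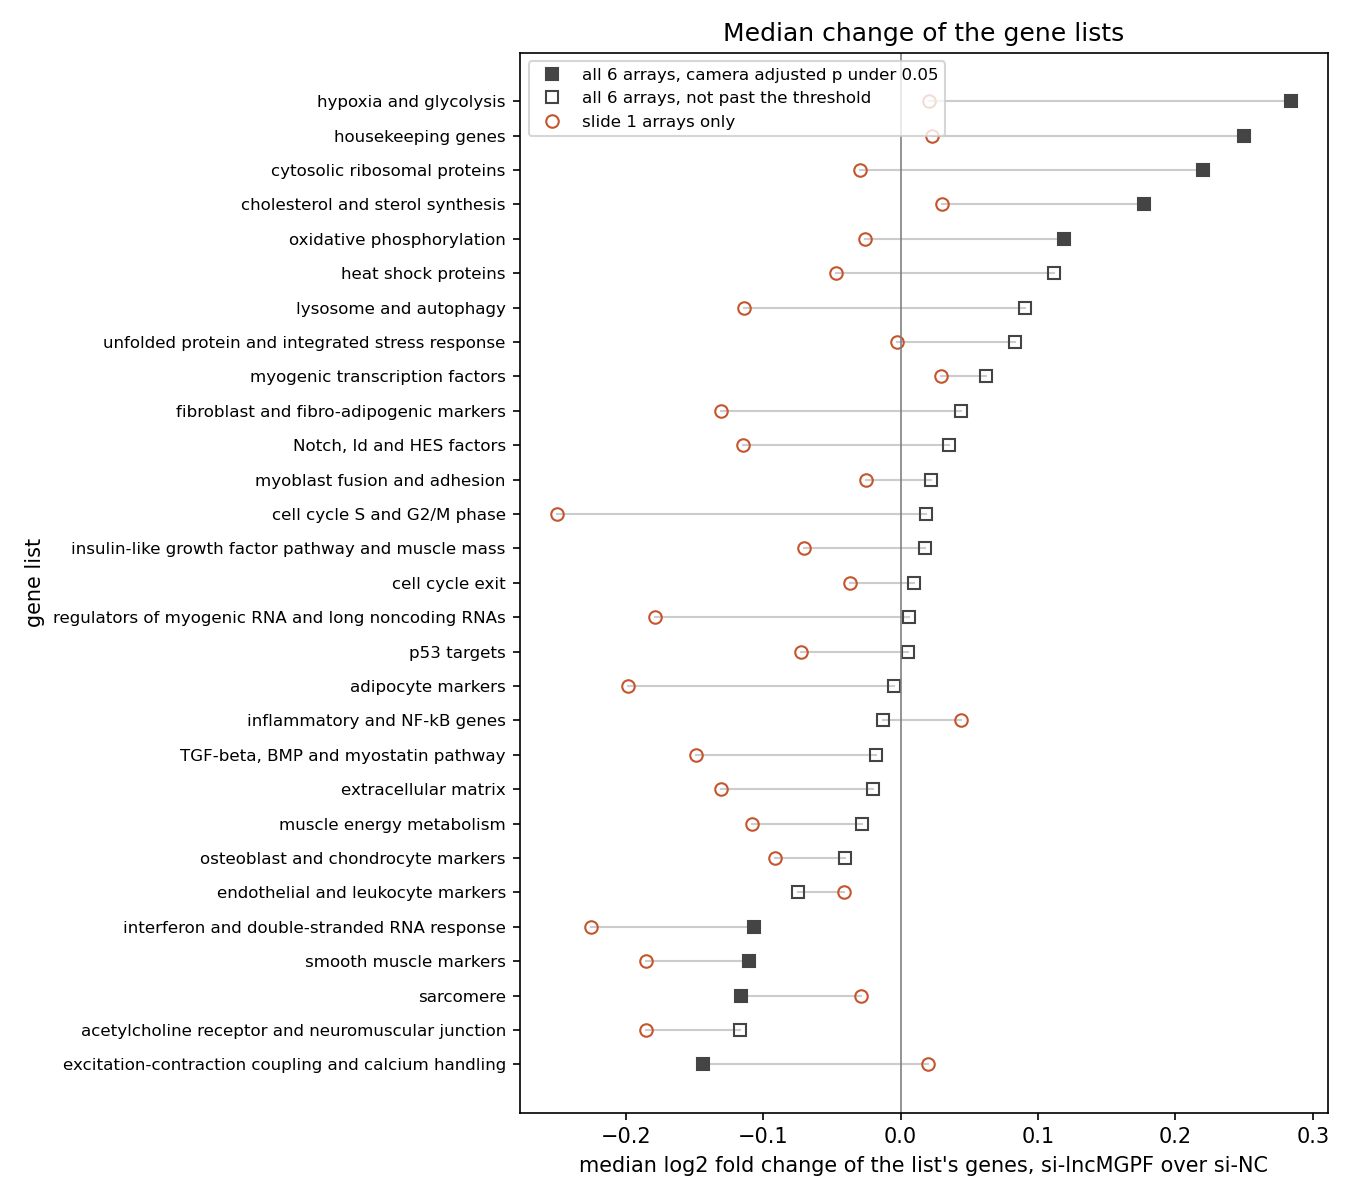
Median log2 fold change of the tested genes of each list, si-lncMGPF over si-NC (x axis, log2 units; lists on the y axis); squares are all 6 arrays, filled where camera's adjusted p was below 0.05, and open circles the slide 1 arrays. The 5 lists highest over all arrays lie between 0.12 and 0.28 there and between -0.03 and 0.03 on slide 1.

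The other lists did not pass as lists. In the TGF-beta, BMP and myostatin list (34 genes, median -0.02, adjusted p = 0.191), 6 members passed when adjusted over the list alone, 1 higher and 5 lower. They included Fst (-0.70), the myostatin antagonist follistatin, the signalling inhibitor Smad6 (-0.43), Ccn2 (-0.39) and Tgfbi (0.43). In the insulin-like growth factor list (26 genes, adjusted p = 0.952), the binding protein genes Igfbp3 (1.39) and Igfbp2 (-0.35) passed when adjusted over the list alone. Among p53 targets (28 genes, adjusted p = 0.848) Trp53i11 did (1.14), as did Adamts5 (-0.56) in extracellular matrix (57 genes, adjusted p = 0.503) and Rbfox1 (-0.61), a splicing regulator, among regulators of myogenic RNA (21 genes, adjusted p = 0.952). Gpnmb in the lysosome list (27 genes, adjusted p = 0.614) and Bglap2 in the osteoblast list (12 genes, adjusted p = 0.952) passed over all probes. In the endothelial and leukocyte list (9 genes, adjusted p = 0.743), Itgam (-1.10 on 1 probe, -0.47 within slide 1 and -1.41 on slide 2) was among the genes that passed when adjusted over the list alone, while its 2 other probes had -0.25 and -0.40. Other probes of genes that passed over their list alone also differed, with 0.17 for Atp2a2, -0.29 for Neb, -0.24 for Xaf1, -0.14 for Adamts5 and -0.03 for Rbfox1. No member passed in either way in the lists of cell cycle exit (19 genes, adjusted p = 0.952), Notch, Id and HES factors (18 genes, 0.743), inflammatory genes (28 genes, 0.614), unfolded protein response (38 genes, 0.0747), heat shock proteins (20 genes, 0.0949), adipocyte markers (8 genes, 0.952) and fibroblast markers (17 genes, 0.743). Myogenic transcription factors as a list had an adjusted p of 0.533. Median, mean and camera direction did not share a sign for the fusion, S and G2/M phase, Notch, insulin-like growth factor, inflammatory, adipocyte and leukocyte lists.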

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

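The normexp run, the slide 1 arrays alone, slide as a random block, the removed signal trend and gene-by-gene array weights were chosen after seeing the data. The 26 called probes kept their direction under each setting that gave them a value, except normexp (24 of 26). Median centring (24 probes), the removed signal trend (25), slide as a random block (30), probes above background on all arrays (23) and the trend with a robust prior (21, but 11 with a fold of at least 2) stayed within 1.5 times the 26, and the series table gave the same values. Quantile normalization called 6 probes (1 higher, 5 lower, 6 with a fold of at least 2, 6 genes), 16.7% of them higher against 26.9%. Normexp called 8 (4 higher, 4 lower, 5 with that fold, 5 genes), 50% of them higher. No filter called 0 in each direction and 0 genes, with 5277 probes at an unadjusted p below 0.05 and more probes to adjust for. The test for a fold over 1.2 called 6 (0 higher, 6 lower, 6 with that fold, 6 genes), and the mean of a gene's probes 34 genes. Slide as a block called 10 (3 higher, 7 lower, 10 with that fold, 9 genes) and 2 lists, and the slide 1 arrays alone, with fewer samples, 1 (0 higher, 1 lower, 1 with that fold, 1 gene) and 2 lists. Array weights by the planned default method called 4 (0 higher, 4 lower, 4 with that fold, 3 genes), but that fit did not converge and weighted si-NC replicate 3 at 721 and si-lncMGPF replicate 3 at 8.81e-05. The gene-by-gene method, tried once that result was known, called 13394 (7244 higher, 6150 lower, 1178 with that fold, 7439 genes), with weights from 0.109 to 9.96. The methods gave si-lncMGPF replicate 3 opposite weights (2.94 by the second), so neither count is relied on. Apart from the settings whose construction gives a reason, the cause was not tested.

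Leaving out each array in turn gave 0 to 4105 probes (0 to 1737 higher, 0 to 2368 lower, 0 to 867 with a fold of at least 2), 0 to 2100 genes and 5 to 10 lists. The highest count came without si-lncMGPF replicate 1, and the 5 lists without si-lncMGPF replicate 2. The replicate block called 0 probes (0 higher, 0 lower, 0 with a fold of at least 2, 0 genes), with 4430 at an unadjusted p below 0.05 and adjusted p of 0.094 to 0.169 for the 26, and 9 lists. Deviations of same-numbered arrays correlated at 0.185, 0.318 and -0.0582, so the numbers were not taken to pair samples. The 9 called lists became 0 with an estimated correlation. The 0 lists called by fry answer another question, since it tests a list against no change. Ms4a18 turned to 0.0898 under normexp (adjusted p 0.81). The signed -log10 p of excitation-contraction coupling turned to 0.191 with slide as a block and 0.476 on slide 1 alone, and that of sarcomere to 0.0444 on slide 1 alone. Over all settings, values of named genes kept direction and side of the threshold in 1020 cases, uncalled genes that stayed uncalled among them. They lost the call in 222, gained it in 31 and changed sign with no call in 130. For lists these numbers were 512, 50, 11 and 62. Only genes called in the main fit can lose a call. Those among the named genes kept it in 6 of 22 settings (Mcpt4) to 14 of 22 (Atp13a4 and Gzme). Lists were not tested with slide as a random block or with the test for a fold over 1.2, and normexp on mean spot signals was not run. Signal over background limits Il7r, Mmel1 and Ms4a18, whose log2 changes ranged up to -0.13, -0.03 and 0.09 across settings. It also limits Atp6v1c2, which had -0.09 under normexp. With normexp 13 of the 21 called genes shrank by over 1.5 times or changed sign. Among them were Atp13a4 (-1.67 to -0.88), Myl2 (-1.51 to -0.74), Clu (-1.43 to -0.85), Try4 (-1.34 to -0.51), Fxyd6 (-1.28 to -0.63) and Gpnmb (-0.88 to -0.30). The offset of 50 shrinks log2 changes of dim probes by construction, and its share in this was not tested.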

Other observations

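Called probes of genes that a brighter probe represents were chosen after their values were seen. The long noncoding RNA 1500009C09Rik was at least 2.06-fold lower in si-lncMGPF on 1 probe (adjusted p = 0.0479), and not well above background on any si-lncMGPF array, while its other probe had a log2 change of -0.66 (adjusted p = 0.395). Slco2b1, an organic anion transporter, was at least 1.64-fold lower on 1 probe, well above background on 1 si-lncMGPF array alone. The other probe of Slco2b1 had a log2 change of -0.92 (limma adjusted p = 0.0735). A probe of Pilra passed the threshold with no fold that can be bounded, while its other probe had -0.35 (limma adjusted p = 0.479). Among probes above background on all arrays, 24 were at least 2-fold lower in si-lncMGPF replicate 1, 279 in replicates 2 and 3 on slide 2, and 7 in both, where independent lists would share 0.311 and unchanged samples simulated against the same si-NC arrays 0.66. For higher probes the numbers were 30, 81 and 3, against 0.113 and 0.7, and 0 probes went in opposite directions. Part of that overlap may come from the shared si-NC arrays, which were not split; with quantile normalization 5 of the 26 called probes kept their call.

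Tests on slide, a smaller response of replicate 1, signal trend and splits of the arrays for probes and genes were chosen after the results were seen, as was the bootstrap spread used for the NRF2 genes and for the interferon and smooth muscle lists. The 26 called probes were weighed against slide, since 2 of the 3 si-lncMGPF arrays were alone on slide 2. On slide 1 the si-lncMGPF array lay beyond the si-NC arrays for 26 probes, with a median ratio of 1.02 to the change over all arrays. The probes were selected for agreement among the 3 si-lncMGPF arrays and the value rests on 1 of them, so slide and knockdown cannot be told apart for these probes. Of 10 splits into 3 and 3 arrays, 1 gave 26 probes and 13 genes with a fitted fold of at least 2, the real one. The highest other gave 0 and 0. Those 13 include Il7r, Mmel1, Ms4a18 and Atp6v1c2, whose bounds lie below 2-fold. That is too few splits for a share below 0.05, and a biological effect of the knockdown stays open as a hypothesis.

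The 9 lists were weighed against slide, scaling and a smaller response of replicate 1. All 9 kept their call at the preset correlation once a signal trend was removed within each array, which argues against scaling that depends on signal as the whole cause of those calls; with an estimated correlation 0 lists were called even before that. The ribosomal median fell from 0.22 to 0.106 and that of oxidative phosphorylation from 0.119 to 0.0699 with that trend, so a part of those changes stays open to it. Of the 7 other than interferon and smooth muscle, 7 lost the call with slide as a block, and their slide 1 medians were between -0.219 and 0.25 of those over all arrays, as slide would give. Signal bears on these medians. Of 5 bins of tested probes by mean signal, the brightest had a median change of -0.112 within slide 1 and 0.129 on slide 2. The dimmest had 0.0503 and -0.0752. A slide 1 median near 0 thus does not show that bright genes were level with probes of like signal in replicate 1. For these 7, slide and a weaker knockdown in replicate 1 cannot be told apart, since slide 1 holds 1 si-lncMGPF array and slide 2 no si-NC array. The smooth muscle list also lost the call with slide as a block, but its median was -0.185 within slide 1 (quartiles -0.61 to -0.107) against -0.11 over all arrays (-0.428 to 0.039) and -0.108 on slide 2. The interferon list was called with slide as a block at the preset correlation, but not with an estimated one (adjusted p = 0.816, and 0.78 without the block). Its median was -0.225 within slide 1, -0.107 over all arrays and -0.000644 on slide 2, so the fall lay in replicate 1 and not on slide 2, where slide would put it. The bootstrap over genes (slide 1 95% interval -0.337 to -0.168, slide 2 -0.104 to 0.0735) takes members as independent, and the slide 1 value rests on 1 si-lncMGPF array. The same holds for smooth muscle (slide 2 interval -0.348 to 0.067), so for both lists slide, a change in replicate 1 alone and the knockdown stay open. The real split gave 9 lists and the highest other 8, with the slide 2 arrays together with si-NC replicate 1, and 1 of 10 splits reached 9, too few for a share below 0.05.

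Higher Nqo1, Gsta2, Gm10639 and Gm3776 raised the hypothesis of a rise of NRF2 target genes, which answer oxidative stress. The 35 other tested targets had a median log2 change of 0.182 over all arrays and 0.0124 within slide 1 (camera p across genes 6.79e-05, and 0.0488 with slide as a block). These p are unadjusted and at the preset correlation, at which other splits of the arrays also called lists. No value with an estimated correlation is given, and the blocked p rests on 1 si-lncMGPF array. Both medians fell short of the level set in advance for a rise. The bound of 0.1 set in advance against a rise was met by the slide 1 value, but not by its spread (bootstrap 95% interval -0.0244 to 0.107). That criterion of spread was added after the value was seen, so the hypothesis stays open. Cross-hybridisation among the glutathione S-transferase transcripts stays open too, with 0 columns of probe sequences in the tables used here. That concerns the 3 members and not Nqo1, which is outside that family.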
